A study of Mus musculus with 15 samples.

How the data were processed

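The data were the 15 scanner output files of the series and its table of values. Per the file headers, every file held a Cy3 scan read with Agilent Feature Extraction 10.7.1.1 or 10.7.3.1 under protocol GE1_107_Sep09, with probe positions in mm9. The signal taken was the processed signal, an intensity which per the file headers was background-subtracted and detrended but not scaled between arrays. The table deposited by the authors held log2 values with the same quartiles on every array, and it tracked the log2 processed signal of each array with r from 0.972 to 0.9999. The labels did not state how that table was made, and its values behaved like quantile-normalized ones, with 110 genes between mHep and eHep from either. Each array held 43379 spots, spots of the same probe were averaged without outlier spots into 41174 probes, and no probe was saturated. Probes were named by RefSeq accession (27668), by the symbol in the file (5589), through an older symbol (471) or kept as in the file (7446), which gave 27343 names, 9043 of them with more than 1 probe. For each gene the probe with the highest mean signal was used.

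Log2 signals were centred on the 75th percentile of each array. A gene was tested where its probe was well above background on all arrays of at least 2 of the 3 mice in eHep or in mHep, or, against primary cells, on the primary array. For mHep against eHep, arrays were averaged per mouse and medium, and limma 3.58.1 in R 4.3.3 fitted medium with mouse as a block on 6 means. Primary cells were compared with the per-mouse means in a fit with the single primary array, whose spread was taken to be that of the cultured means. Within 129S1-No1 and C57B6-No1, the 12 arrays were fitted by mouse and medium, which also gave the difference of the changes and the difference of the levels between these mice. Adjusted p-values came from limma's moderated statistic with the Benjamini-Hochberg correction. The threshold was 0.05, and a log2 difference of at least 1 was also required against primary cells. The comparisons, thresholds, lists and alternatives were chosen before the data were examined. The same mouse paired the eHep and mHep arrays per the labels, and the deviations of a mouse in eHep and mHep correlated at 0.40 for 129S1-No1, 0.56 for C57B6-No1 and 0.54 for 129S1-No2, while those of different mice reached 0.0114 at most.

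Of 33 fixed gene lists, 32 were tested with camera at a preset correlation of 0.01 and, as an alternative, with an estimated correlation and with fry. The remaining list, Y-linked genes and Xist, served only to describe the cells. Camera on the differences between the mice was added after the values were seen. "Adjusted over the list alone" means that the correction was made over the members of that list only. The genes named were the 12 largest differences per direction for mHep against eHep, 8 against primary cells and 6 between mice, up to 4 members of each list, and a fixed set of liver and cell cycle genes. For mHep against eHep they had to change the same way in all 3 mice, and clone and predicted names were skipped. Genes dark on all arrays of a group, or of a mouse in the comparisons of mice, were left out of the largest differences, which was not part of the rule as first fixed. Some genes that the rule names are not reported here. Where any array of the lower group was dark, readings of that group under the lowest signal called well above background on their array were raised to it and the fold was given as a bound. The distance to primary cells was compared with the step from eHep to mHep by Fisher's exact test, 50 simulations of unchanged mHep and a split by mouse. In a self-test, 200 genes were given known changes of log2 1, 2, 4 or 8, with 50 at each size. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15, and tables were read with version 1.17.8 of data.table.

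Alternatives tried were normexp background with an offset of 50, quantile normalization, median scaling, the 75th percentile of probes detected on all arrays, the value table of the authors, no filter, a strict filter, the mean of all probes, a trended robust moderation, slide as a block, no mouse block, arrays as samples with a fixed or random mouse term, weighted means, leaving out mice, replicates or arrays, a fold limit, and the C57B6 mouse alone against primary cells. Fits within a scan, with scan as a block or with all readings under the background limit raised to it were added after the data were seen. The earlier scan held the primary array, both arrays of 129S1-No2 and replicate 3 of C57B6-No1. The later scan held all arrays of 129S1-No1 and the other replicates of C57B6-No1. Values by scan therefore also differ in the mice they hold. A slide block needs single arrays as samples, since the arrays of a mouse lay on several slides, so for comparisons of mouse means it changed the unit too, as did the earlier scan and the C57B6 mouse alone against primary cells. All eHep arrays of 129S1-No1 lay on 1 slide and all its mHep arrays on another. A slide block therefore cannot part medium from slide within that mouse. The array mHep 3 was alone on its slide, so for mHep against eHep a slide block left 129S1-No2 without weight. The array titled mHep 3 had a source name of eHep and was kept as mHep. Its correlation with the other mHep arrays was 0.873 to 0.937, and with the eHep arrays 0.849 to 0.890. Sequence variants and copy number were not analysed here. With 1 primary array and 3 mice, the number of arrays limits the precision of every comparison.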

Results

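Gene expression was measured on 15 Agilent 1-colour mouse arrays in expandable hepatocytes grown for 21 days and in freshly isolated primary hepatocytes. The labels named 7 eHep arrays and 7 mHep arrays from 3 mice and 1 primary hepatocyte array. The labels did not spell out the name mHep, which was taken to mean the expandable hepatocytes grown in differentiation medium, with eHep as the cells in expansion medium. The mice were 129S1-No1 (3 eHep and 3 mHep arrays), C57B6-No1 (3 and 3) and 129S1-No2 (1 and 1), and the primary cells came from C57B6 mice. The mHep array of 129S1-No2 carried an eHep source name and was placed by its title. Between 48.8% and 61.9% of probes were well above background on the cultured arrays, against 36.3% on the primary array. Of 27343 named genes, 14597 were bright enough to compare mHep with eHep. Gene levels are given as log2 signal relative to the 75th percentile of the same array, as mean ± SD over 3 mouse means, and differences as log2 mHep minus eHep ± SE unless another comparison is named. Where any array of the lower group was not well above background, the fold is given as "at least N-fold", with readings of that group under the background limit of their array raised to it, while log2 differences keep the readings as measured.

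Genes for secreted plasma proteins rose from eHep to mHep in all 3 mice. Ahsg, which encodes the liver glycoprotein fetuin-A, rose at least 2127-fold (log2 difference 11.78 ± 0.64, adjusted p = 0.00197, n = 3 mice). Its level went from -4.81 ± 2.58 in eHep to 6.96 ± 1.45 in mHep. Alb, the gene of serum albumin, rose 533-fold (log2 difference 9.06 ± 0.84, adjusted p = 0.00993), from -1.61 ± 2.87 to 7.45 ± 0.60. Fgg, a chain of fibrinogen, rose at least 739-fold (log2 difference 10.63 ± 0.42, adjusted p = 0.00175), and Apoa1, the main protein of high-density lipoprotein, rose at least 429-fold (log2 difference 10.07 ± 0.92, adjusted p = 0.00932). The drug-metabolising cytochrome Cyp2d10 rose at least 359.7-fold (log2 difference 8.96 ± 0.41, adjusted p = 0.00175). In the other direction, the receptor phosphatase gene Ptprb fell at least 56.2-fold (log2 difference -6.49 ± 0.42, adjusted p = 0.00330), the prostaglandin synthase gene Ptgs2 fell at least 21.9-fold (log2 difference -4.92 ± 0.39, adjusted p = 0.00627) and the mitotic cyclin gene Ccnb1 fell at least 18.0-fold (log2 difference -4.19 ± 0.53, adjusted p = 0.0263). The probe of Alb (NM_009654) lay on chromosome 5 from 90901598 to 90901657 in the mm9 build, and that of Ahsg (NM_013465) on chromosome 16 from 22899415 to 22899474.

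In all, 268 of 14597 genes passed an adjusted p of 0.05 between mHep and eHep, 202 higher and 66 lower in mHep. Each of them changed at least 2-fold and had the same sign in all 3 mice. The largest further rises were in Fabp1 (9.46 ± 1.48), Saa2 (9.36 ± 1.36), Serpina1d (9.20 ± 0.44), Apoc3 (9.11 ± 1.23), F10 (8.84 ± 0.45), Apoh (8.81 ± 0.40) and Cyp3a41a (8.66 ± 1.01). The largest further falls were in Acsbg1 (-5.94 ± 0.59), Lmcd1 (-5.00 ± 0.56), Tnnt2 (-4.39 ± 0.57), Ripor2 (-4.28 ± 0.63), Pcolce2 (-4.20 ± 0.47), Espl1 (-4.07 ± 0.49), Fxyd5 (-3.95 ± 0.46), Prrx2 (-3.74 ± 0.60) and Padi2 (-3.72 ± 0.49). Among the genes that passed, 32 were not well above background on any eHep array and 6 on any mHep array. In 180 of the 268 genes at least 1 array of the lower group was not well above background. With every reading under the background limit raised to it, 288 genes passed, and of the genes named here Prrx2, Fbp1 and Apoa4 no longer did. Ttr, the gene of the thyroxine carrier transthyretin, rose at least 55.9-fold (adjusted p = 0.00197). The beta-catenin target Axin2 fell at least 6.54-fold (adjusted p = 0.0162). The count was 829 without 129S1-No1, 513 without C57B6-No1 and 656 without 129S1-No2. Without mouse as a block 2 genes passed, within the earlier scan 1520 and within the later scan 470. With the 14 arrays as samples 5024 genes passed, and 3006 with slide as a further block.

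The balance of higher and lower genes depended on the unit and on the scaling of the arrays. Of the genes that passed on the mouse means 75.4% were higher in mHep, against 38.5% over 14 arrays and 35.7% over 14 arrays with slide as a block. The median of all genes was -0.10 with the 75th percentile scaling and 0.018 with the 75th percentile of probes detected on all arrays, where 96 genes were higher and 9 lower. Quantile normalization gave 94 higher and 16 lower, and the value table of the authors gave 94 higher and 16 lower. Several genes of hepatocyte identity did not pass: Afp, the fetal form of albumin (1.17 ± 0.43, adjusted p = 0.291), the nuclear receptor Hnf4a (1.37 ± 0.40, adjusted p = 0.191) and the urea cycle gene Cps1 (adjusted p = 0.0731). Cyp3a11 did not pass either (adjusted p = 0.122), with differences of 11.05 in 129S1-No1, 8.18 in C57B6-No1 and 1.57 in 129S1-No2. The epithelial gene Cdh1 (adjusted p = 0.694) and the filament gene Vim (-1.64 ± 0.48, adjusted p = 0.194) did not pass. Cell cycle genes Mki67 (adjusted p = 0.2998), Top2a (adjusted p = 0.0609), Cdkn1a (adjusted p = 0.668), Cdkn2a (adjusted p = 0.489) and Trp53 (adjusted p = 0.216) did not pass singly. Col1a1, a collagen chain, was well above background on 3 eHep arrays and 0 mHep arrays. Simulated changes showed what 3 mice can find where a gene changes equally in each. Changes of log2 1, 2, 4 and 8 were recovered in 0%, 28%, 100% and 100% of 50 genes each, with 11 false calls. Genes whose change varies between mice, such as Cyp3a11, can be missed at these sizes.

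Lists of hepatocyte function, fixed before the data were examined, moved up from eHep to mHep. For the plasma proteins, 10 of 22 measured genes rose and 18 did so adjusted over the list alone, among them Ahsg, Fgg and Apoh (list median 5.98, adjusted p = 5.5e-23, adjusted p = 0.194 with an estimated correlation). The list medians in 129S1-No1, C57B6-No1 and 129S1-No2 were 4.16, 6.25 and 7.44. Within the earlier and later scan the median was 7.36 and 4.81, with slide as a block 6.02, and with genes at their bound 5.86. Among cultured arrays the earlier scan held only 129S1-No2 and replicate 3 of C57B6-No1, and only the later scan held 129S1-No1. Differences between scans are thus mixed with differences between mice, here and below. For complement and coagulation, the blood cascades fed by the liver, 7 of 23 measured genes rose and 16 did so adjusted over the list alone, among them Serpinf2 (4.95 ± 0.44) and C4b (4.91 ± 0.59) (list median 2.62, adjusted p = 5.5e-17, adjusted p = 0.194 with an estimated correlation). The complement median was 3.38 in the earlier and 2.21 in the later scan, 3.06 with slide as a block and 2.10 with bounds. For cytochrome P450 and phase I genes, which oxidise drugs and steroids, 4 of 20 measured genes rose and 15 did so adjusted over the list alone, among them Cyp2d22 (5.02 ± 0.55), Fmo5 (3.25 ± 0.43) and Cyp4a10 (3.12 ± 0.43) (list median 3.35, adjusted p = 2.6e-14, adjusted p = 0.194 with an estimated correlation). The P450 median was 3.30 in the earlier and 3.23 in the later scan, 3.28 with slide as a block and 3.18 with bounds. For conjugation and transport, 5 of 19 measured genes rose and 10 did so adjusted over the list alone, among them Sult1a1 (8.52 ± 0.61), Sult1d1 (7.78 ± 0.55), Ugt2b5 (5.11 ± 0.50) and Ugt2b36 (4.72 ± 0.55) (list median 2.12, adjusted p = 1.3e-11, adjusted p = 0.257 with an estimated correlation). The conjugation median was 1.53, 1.73 and 2.57 by mouse, 1.26 without 129S1-No2, 2.42 in the earlier and 1.22 in the later scan, and 1.44 with slide as a block. Normexp background gave smaller medians, 4.09 for plasma proteins, 1.37 for complement, 2.12 for P450 and 1.38 for conjugation. With a mouse left out 12 to 16, 9 to 14, 11 to 12 and 7 to 8 genes of these lists rose, and 19, 15, 15 and 13 over 14 arrays.

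**Figure D1:**
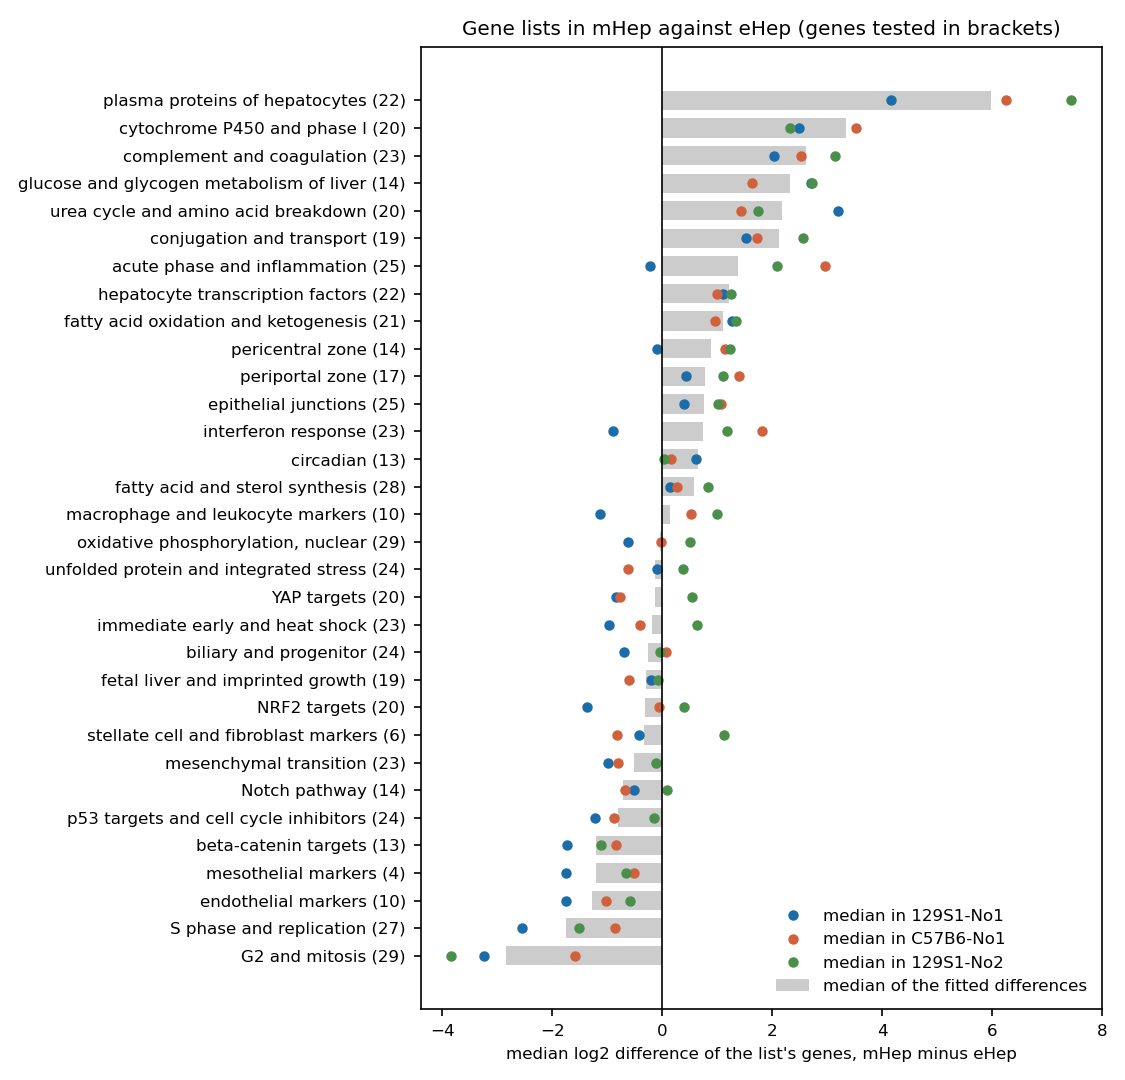
Median mHep minus eHep log2 difference of the fixed gene lists in each of the 3 mice.

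Metabolic lists moved up as well, most of them with single genes that rose. In glucose and glycogen metabolism, 4 of 14 genes rose, 11 adjusted over the list alone, among them G6pc (6.69 ± 0.77), the glucose carrier Slc2a2 (5.10 ± 0.71) and Fbp1 (at least 13.4-fold). Their median was 2.32 (adjusted p = 2.5e-13, adjusted p = 0.257 with an estimated correlation). In the urea cycle and amino acid breakdown, which clear ammonia, 4 of 20 genes rose, among them Prodh2 (3.74 ± 0.54), Aass (3.69 ± 0.49) and Nags (3.42 ± 0.39). Here 12 rose and 1 fell adjusted over the list alone, with a median of 2.19 (adjusted p = 5.2e-08, adjusted p = 0.194 with an estimated correlation), and 3.20, 1.43 and 1.75 in 129S1-No1, C57B6-No1 and 129S1-No2. It was 1.15 with normexp background and 3.11 with slide as a block. In fatty acid oxidation and ketogenesis, 3 of 21 genes rose, 7 adjusted over the list alone, including the nuclear receptor Ppara (5.58 ± 0.67) and Ehhadh (2.54 ± 0.41), and the median was 1.11 (adjusted p = 5.6e-11, adjusted p = 0.194 with an estimated correlation). In fatty acid and sterol synthesis 0 of 28 genes passed singly, and the median was 0.57 (adjusted p = 0.00136, adjusted p = 0.383 with an estimated correlation). That median was small in some mice and scans: 0.14, 0.27 and 0.83 in 129S1-No1, C57B6-No1 and 129S1-No2, 0.32 without 129S1-No2 and 0.13 within the later scan. Of the hepatocyte transcription factors, which set the liver programme, 4 of 22 rose and 10 did so adjusted over the list alone: Creb3l3 (6.16 ± 0.38), Nr5a2 (4.68 ± 0.65), Rora (3.35 ± 0.40) and the bile acid receptor Nr1h4 (3.18 ± 0.47). The median was 1.22 (adjusted p = 9.0e-09, adjusted p = 0.194 with an estimated correlation). In epithelial junctions 3 of 25 genes rose and 4 did so adjusted over the list alone: the connexins Gjb2 (5.66 ± 0.80) and Gjb1 (4.01 ± 0.45), and Ceacam1 (4.57 ± 0.39), with a median of 0.75 (adjusted p = 1.7e-06, adjusted p = 0.325 with an estimated correlation). The junction median was 0.40, 1.07 and 1.02 by mouse, 1.26 within the earlier and 0.54 within the later scan. With a mouse left out 5 to 7 glucose, 8 to 9 urea cycle, 4 to 5 oxidation and 0 synthesis genes rose, and 6 to 8 transcription factors and 3 to 5 junction genes, against 12, 12, 17, 7, 15 and 12 over 14 arrays.

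Among genes of the periportal zone of the lobule, 4 of 17 rose, among them Hsd17b13 (6.11 ± 0.38) and Apoa4 (at least 75.1-fold), and 8 rose and 2 fell adjusted over the list alone (median 0.78, adjusted p = 3.3e-05, adjusted p = 0.194 with an estimated correlation). Their median was 2.28 within the earlier scan, 0.25 within the later scan, 1.94 with slide as a block, 0.51 with normexp background and 0.47 without C57B6-No1. Rnase4, counted with the pericentral zone, rose (2.74 ± 0.44), and 1 of 14 pericentral genes rose and 1 fell, 6 and 2 adjusted over the list alone (median 0.88, adjusted p = 0.0252, adjusted p = 0.448 with an estimated correlation). The pericentral medians of 129S1-No1, C57B6-No1 and 129S1-No2 were -0.091, 1.15 and 1.23, and 1.32, 0.56 and 0.75 with these mice left out. In acute phase and inflammation, 7 of 25 genes rose, including Serpina3n (5.85 ± 0.55), Saa4 (5.81 ± 0.51) and Orm2 (5.24 ± 0.42). There 10 rose and 1 fell adjusted over the list alone, and the median was 1.39 (adjusted p = 7.0e-09, adjusted p = 0.420 with an estimated correlation). The medians by mouse were -0.22, 2.97 and 2.09, in the same order. With these mice left out they were 2.55, 0.83 and 1.68, and 7 to 14 genes rose. Of the interferon response genes 0 of 23 passed, 1 adjusted over the list alone, with a median of 0.74 (adjusted p = 3.8e-04, adjusted p = 0.540 with an estimated correlation). The interferon medians by mouse were -0.90, 1.81 and 1.18, with 1.72 within the earlier scan, 0.40 within the later scan and 0.97 with slide as a block. Without 129S1-No1, C57B6-No1 or 129S1-No2 the median was 1.53, 0.14 and 0.78, and 9, 0 and 1 of the genes rose.

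Genes of cell division fell from eHep to mHep. In G2 and mitosis, 6 of 29 genes fell, among them the centromere histone Cenpa (-3.52 ± 0.51), the spindle kinase Aurka (-3.20 ± 0.50) and Kif20a (-3.20 ± 0.51), and 26 fell adjusted over the list alone. The median was -2.84 (adjusted p = 3.6e-20, adjusted p = 0.325 with an estimated correlation), and -3.24, -1.59 and -3.84 in 129S1-No1, C57B6-No1 and 129S1-No2. It was -3.26 within the earlier scan, -2.24 within the later scan and -2.91 with slide as a block. In S phase and replication, 1 of 27 genes fell, the DNA polymerase gene Pole (-2.76 ± 0.42), and 21 fell adjusted over the list alone. Its median was -1.74 (adjusted p = 2.0e-13, adjusted p = 0.383 with an estimated correlation), -2.54, -0.86 and -1.52 by mouse, and -1.81, -1.43 and -2.31 within the earlier scan, within the later scan and with slide as a block. Of the beta-catenin targets 1 of 13 fell, and 1 rose and 4 fell adjusted over the list alone (median -1.20, adjusted p = 0.00321, adjusted p = 0.257 with an estimated correlation). Their median was -1.74, -0.85 and -1.12 by mouse, -0.72 within the earlier and -1.41 within the later scan. None of 10 endothelial markers passed singly and 4 fell adjusted over the list alone, with a median of -1.28 (adjusted p = 0.00333, adjusted p = 0.257 with an estimated correlation). The endothelial median was -1.75, -1.03 and -0.59 by mouse, -0.63 without 129S1-No1, -0.49 within the earlier and -1.59 within the later scan, and -0.30 with normexp background. With a mouse left out 15 to 24 G2 and mitosis genes, 1 to 3 S phase genes, 3 to 4 beta-catenin targets and 0 to 2 endothelial markers fell, against 24, 27, 7 and 6 over 14 arrays.

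Other lists did not pass between mHep and eHep. Of the biliary and progenitor genes 1 of 24 rose, Ly6d, at least 70.8-fold (adjusted p = 0.00510), while Krt19 (-0.60 ± 0.94, adjusted p = 0.830), Krt7 (0.83 ± 0.79, adjusted p = 0.697), Sox9 (adjusted p = 0.160), Epcam (adjusted p = 0.249) and Spp1 (adjusted p = 0.550) did not pass. Their median was -0.26, their mean 0.13, the direction of the test up (adjusted p = 0.944), and 2 rose and 3 fell adjusted over the list alone. Fetal liver and imprinted genes had a median of -0.30 (adjusted p = 0.224), with 1 of 19 lower adjusted over the list alone, and mesenchymal transition genes a median of -0.52 (adjusted p = 0.0849), with 2 of 23 lower adjusted over the list alone. The 6 stellate cell genes had a median of -0.34, a mean of 0.78 and a test direction up (adjusted p = 0.417), with 2 higher adjusted over the list alone. Unfolded protein genes had a median of -0.13, a mean of -0.0029 and a test direction up (adjusted p = 0.679). Medians of the remaining lists were 0.14 for 10 macrophage genes (adjusted p = 0.522), -1.21 for 4 mesothelial genes (adjusted p = 0.118), -0.81 for 24 p53 targets (adjusted p = 0.101) and -0.14 for 20 YAP targets (adjusted p = 0.211). They were -0.31 for 20 NRF2 targets (adjusted p = 0.579), -0.041 for 29 oxidative phosphorylation genes (adjusted p = 0.912) and 0.66 for 13 circadian genes (adjusted p = 0.0724), and no member of these 7 lists passed over all genes or adjusted over the list alone. Immediate early genes had a median of -0.18 (adjusted p = 0.224), with 1 of 23 lower adjusted over the list alone. Notch pathway genes had a median of -0.72 (adjusted p = 0.224), with 1 higher and 1 lower adjusted over the list alone. Of 5 genes kept to describe sex, Xist and the Y-linked genes, 4 were bright enough to test and 0 passed over the 3 mice. Their medians in 129S1-No1, C57B6-No1 and 129S1-No2 were 2.13, 0.28 and -0.81. Within 129S1-No1 2 of the 4 rose and 0 fell, and within C57B6-No1 0 passed. The change of 1 gene was more negative in C57B6-No1 than in 129S1-No1, and 1 gene was higher in C57B6-No1 over both media. The cause was not tested.

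**Figure D2:**
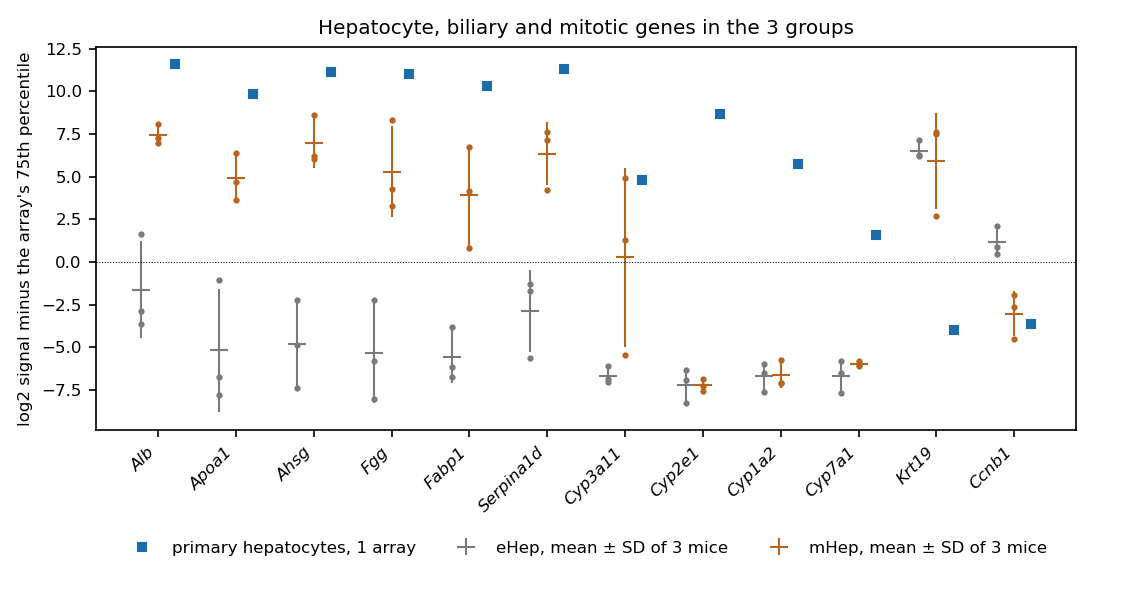
Levels of hepatocyte genes in eHep, mHep and primary cells, as log2 signal relative to the 75th percentile of each array.

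Against freshly isolated primary hepatocytes, eHep were lower in the genes of mature liver function and higher in single genes such as Vim, Tuba1a, Phgdh and Pkm. Serpina3k, a liver protease inhibitor, was at least 73721-fold lower in eHep (log2 difference -17.02 ± 2.43, adjusted p = 0.00689, n = 3 mice against 1 primary array). Alb was 9312-fold lower (log2 difference -13.18 ± 1.91, adjusted p = 0.00711). Cyp2e1, which oxidises ethanol, was not well above background on any cultured array and was at least 11526-fold lower in eHep (adjusted p = 0.00111). Phgdh, the first enzyme of serine synthesis, was 617-fold higher (log2 difference 9.27 ± 0.70, adjusted p = 0.00149), and Vim, an intermediate filament of mesenchymal cells, was 337-fold higher (log2 difference 8.40 ± 0.73, adjusted p = 0.00201). The biliary keratins Krt7 and Krt19 were at least 511-fold (adjusted p = 0.00369) and at least 401-fold (adjusted p = 0.0138) higher. Other large differences were Timp2 (8.76 ± 0.75), Tuba1a (7.91 ± 1.09), Pkm (7.75 ± 0.82), Lgals3 (7.70 ± 0.87), Ezr (7.33 ± 0.89) and Tmsb10 (7.21 ± 0.72) on the higher side. On the lower side were Fgg (-16.34 ± 2.54), Apoa2 (-16.11 ± 4.004), Mup4 (-16.09 ± 2.60), Ahsg (-15.94 ± 1.93), F10 (-15.92 ± 2.20), Fabp1 (-15.89 ± 2.16) and Serpina1c (-15.70 ± 2.12). Cyp1a2 was at least 1542-fold and Cyp7a1 at least 86.7-fold lower, and Hnf4a was 10.4-fold lower (adjusted p = 0.0326).

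Of 15168 genes, 2279 passed between eHep and primary cells, 852 higher and 1427 lower in eHep. The primary array was not well above background for 586 of the higher genes, and no eHep array was for 382 of the lower ones. The primary array was dim, with a 75th percentile of 6.29 against 7.96 to 9.69 on the others. The median of all genes was -0.19 with the 75th percentile scaling, -0.41 with normexp background and 0.32 with quantile normalization. Quantile normalization gave 1701 higher and 1298 lower, median scaling 1149 higher and 1235 lower, detected probes 1193 higher and 1305 lower, and the value table of the authors 1704 higher and 1298 lower. With single arrays in place of mouse means, slide as a block gave 7780 genes, the earlier scan alone 5489, and the C57B6 mouse alone 4959. On mouse means all mice but C57B6-No1 gave 429. Simulated changes of log2 1, 2, 4 and 8 were recovered in 0%, 0%, 22% and 86% of genes, with 3 false calls.

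By list, 22 of 25 urea cycle and amino acid genes (23 adjusted over the list alone) and 16 of 24 plasma protein genes (23 adjusted over the list alone) were lower in eHep than in primary cells, with medians of -11.27 and -11.31. The same held for 19 of 30 complement and coagulation genes, 18 of 25 conjugation genes, 17 of 25 P450 genes and 17 of 22 periportal genes, with 27, 21, 20 and 18 adjusted over the list alone. Lower were also 13 of 22 fatty acid oxidation genes, 13 of 24 transcription factors, 12 of 19 pericentral genes, 11 of 15 glucose genes and 6 of 29 fatty acid and sterol synthesis genes, with 18, 15, 18, 13 and 16 adjusted over the list alone. Of the markers of other liver cells, 9 of 19 macrophage genes and 4 of 14 endothelial genes were lower in eHep, with 11 and 9 adjusted over the list alone. By contrast 0 of 7 stellate genes and 0 of 4 mesothelial genes were lower, and 1 mesothelial gene was higher. Higher in eHep were 10 of 20 YAP targets, which answer to cell shape and stiffness, 6 of 29 G2 and mitosis genes and 6 of 23 mesenchymal genes, with 14, 8 and 10 adjusted over the list alone and medians of 3.06, 3.34 and 1.83. Higher were also 6 of 24 biliary genes, 5 of 24 p53 targets and 5 of 19 fetal genes, with 6, 9 and 6 adjusted over the list alone and medians of 1.62, 2.03 and 1.70. These medians depended on the processing. With quantile normalization, normexp background and genes at their bound they were 3.22, 0.93 and 1.16 for biliary genes, 2.15, 1.47 and 1.76 for p53 targets and 3.13, 1.45 and 1.0503 for fetal genes. In the same order they were 4.63, 2.10 and 2.91 for YAP targets, 3.55, 2.04 and 2.49 for G2 and mitosis genes and 2.51, 1.38 and 1.77 for mesenchymal genes. Acute phase genes were split, with 4 higher and 8 lower, as were unfolded protein genes, with 6 higher and 4 lower. The median of the unfolded protein genes was -0.80 here and 0.61 with quantile normalization, and that of the stellate genes -1.70 and 1.11. For NRF2 targets it was -0.019 and 1.21, and for immediate early genes, of which 5 were higher, -0.32 and 0.51. With genes at their bound, the medians of plasma proteins, P450 and complement genes were -10.79, -10.23 and -9.12.

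Enzymes of the mature lobule were lower in mHep than in primary cells, while Alb did not pass (log2 difference -4.13 ± 1.91, adjusted p = 0.214). Cyp2e1 was at least 12299-fold lower in mHep (adjusted p = 0.00126), Cyp1a2 at least 1599.7-fold and Cyp7a1, which starts bile acid synthesis, at least 91.3-fold. Mup3, a major urinary protein, was at least 33935-fold lower (log2 difference -15.76 ± 1.28, adjusted p = 0.00232), and the growth factor gene Igf1 was at least 7283-fold lower (log2 difference -13.09 ± 1.38, adjusted p = 0.00365). Timp2, an inhibitor of matrix proteases, was 431-fold higher (log2 difference 8.75 ± 0.75, adjusted p = 0.00238), and Krt7 was at least 906-fold and Krt19 at least 264-fold higher. Other large differences were Ces3b (-15.36 ± 1.32), Mug2 (-14.66 ± 1.15), Akr1c6 (-14.32 ± 1.57), Hpd (-13.80 ± 1.46), Agxt (-13.42 ± 1.76) and Slc22a7 (-12.90 ± 1.29) on the lower side. On the higher side were Phgdh (8.14 ± 0.70), Tuba1a (7.44 ± 1.09), Ezr (7.10 ± 0.89), Klf6 (7.04 ± 0.54), Cd14 (6.96 ± 0.89), Slco3a1 (6.88 ± 0.93) and Pkm (6.84 ± 0.82). In mHep 0 of 24 plasma protein genes passed as lower than in primary cells over all genes, and 5 did so adjusted over the list alone. Their median was still -4.55, and simulated changes of log2 4 were recovered in only 30% of genes in this comparison. Lower were 14 of 25 urea cycle and amino acid genes (median -8.28), 12 of 19 pericentral genes (median -6.51), 11 of 30 complement genes, 10 of 25 P450 genes and 10 of 22 periportal genes, with 20, 15, 18, 16 and 16 adjusted over the list alone. Of the transcription factors 3 of 24 were lower, and of the glucose genes 3 of 15, against 4 and 10 adjusted over the list alone. Higher in mHep were 9 of 20 YAP targets, 7 of 24 biliary genes, 5 of 19 fetal genes and 4 of 24 p53 targets, with 11, 8, 6 and 4 adjusted over the list alone, and 0 of 29 G2 and mitosis genes.

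Of 15168 genes, 1514 passed between mHep and primary cells, 608 higher and 906 lower in mHep. Of the higher ones 434 were dark on the primary array, and of the lower ones 249 were dark on every mHep array. The median of all genes was -0.34 with the 75th percentile scaling and 0.25 with that of detected probes. Quantile normalization gave 1305 higher and 819 lower, normexp background 282 higher and 672 lower, median scaling 815 higher and 771 lower, detected probes 923 higher and 789 lower and the value table of the authors 1302 higher and 817 lower. With quantile normalization the median was 0.72 for acute phase genes, against -0.84 with the 75th percentile. With single arrays in place of mouse means, slide as a block gave 7535 genes, the earlier scan alone 3997, and the C57B6 mouse alone 4059. On mouse means all mice but C57B6-No1 gave 102. Simulated changes of log2 1, 2, 4 and 8 were recovered in 0%, 0%, 30% and 90% of genes, with 2 false calls.

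The step from eHep to mHep closed part of the distance to primary cells for genes of liver function. Distances and the percent closed were taken on the log2 scale, so they are not shares of the expression level regained. Plasma protein genes closed a median of 59.6% (16 genes) of their distance, epithelial junction genes 47.8% (5 genes), acute phase genes 46.7% (8 genes) and transcription factors 41.4% (13 genes). Glucose genes closed 32.7% (11 genes), fatty acid oxidation genes 27.0% (13 genes), complement genes 26.6% (19 genes), P450 genes 26.2% (17 genes), conjugation genes 21.0% (18 genes) and urea cycle and amino acid genes 16.6% (22 genes). Periportal genes closed 15.6% (17 genes) and fatty acid and sterol synthesis genes 14.7% (6 genes), whereas pericentral genes closed 1.24% (12 genes), macrophage genes -1.98% (9 genes) and beta-catenin targets -14.2% (5 genes). Of 971 genes lower in eHep than in primary cells and measured in both comparisons, 155 rose to mHep (15.96%), and 1 fell further. Among 13626 other genes 47 rose (0.345%), an odds ratio of 54.8 (Fisher's exact p = 3.2e-143). Here and below, Fisher's test counts genes of the same mice as independent, so its p does not measure the spread between mice. The share of lower genes that rose was 31.0%, 58.4% and 28.8% without 129S1-No1, C57B6-No1 or 129S1-No2, 40.3% with the C57B6 mouse alone and 9.45% with quantile normalization. Of 852 genes higher in eHep, 15 fell to mHep (1.76%), against 51 of 13745 others (0.371%, odds ratio 4.81, Fisher's exact p = 4.5e-06). Their share was 5.18%, 0.781% and 8.81% with these mice left out, 39.4% with the C57B6 mouse alone and 0.353% with quantile normalization. Without C57B6-No1 the 0.781% lay below the share of other genes in that fit. The lower genes closed a median of 22.4% of their distance and the higher ones 9.85%, and 97.9% and 98.1% remained at least 2-fold apart.

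The same eHep values enter the distance and the step, so unchanged mHep values were simulated 50 times. They closed 3.04% on average for the lower genes (highest 3.94%) and 3.16% for the higher genes (highest 4.71%). Next the distance was taken from 2 mice, with genes at least 4-fold lower or higher, and the step from 129S1-No1, C57B6-No1 or 129S1-No2 alone. Then 24.2%, 31.3% and 44.0% of lower genes rose at least 2-fold, against 15.1%, 9.25% and 12.5% of others. The same split for the higher genes gave 35.8%, 23.4% and 25.04%, against 24.5%, 9.57% and 12.7%. The median steps of the lower genes were -0.26, 0.38 and 0.77, the first of them away from primary cells. Those of the higher genes were -0.41, -0.29 and -0.22. In 129S1-No1 the median of all genes tested between mHep and eHep was itself -0.37 with this scaling, and 0.037 with that of detected probes. The steps and the percent closed in that mouse include this offset, so their direction cannot be told apart from the scaling. By mouse, the 971 lower genes closed 18.0%, 20.8% and 26.8%, and 69.4%, 82.5% and 89.2% of them moved towards primary cells, against 57.8% with unchanged mHep values averaged over mice. These genes had to be bright in eHep or mHep, which favours genes that rose. Over all 1427 lower genes 8.07%, 10.8% and 16.9% was closed, and 57.7%, 77.8% and 83.6% moved towards primary cells. The higher genes closed 14.9%, 10.4% and 5.75%.

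**Figure D3:**
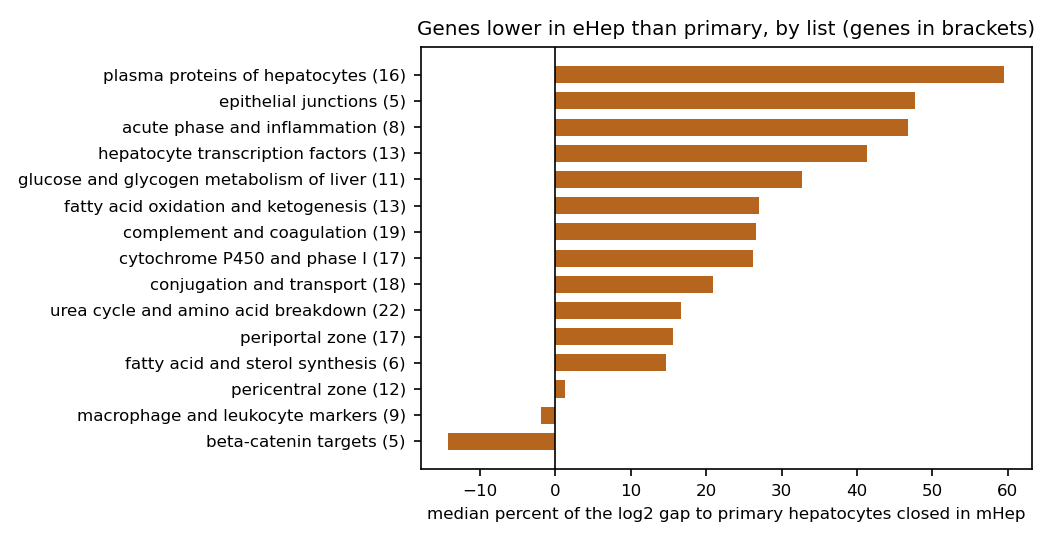
Part of the log2 distance between eHep and primary cells closed in mHep, by gene list.

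Ahsg and Alb rose within each mouse that had 3 arrays per medium: Ahsg by 10.85 in 129S1-No1 and 10.89 in C57B6-No1 (SE 0.64 in each), and Alb by 6.44 in 129S1-No1 and 10.57 in C57B6-No1 (SE 0.28 in each). Fgg rose by 10.53 in 129S1-No1 and 10.08 in C57B6-No1, and the mitotic Ccnb1 changed by -5.40 in 129S1-No1 and -3.14 in C57B6-No1. Of the plasma protein genes 14 of 22 rose in 129S1-No1 and 17 in C57B6-No1, with medians of 4.16 and 6.25, and 3.69 and 4.11 with normexp background. Of the G2 and mitosis genes 23 of 29 fell in 129S1-No1 and 17 in C57B6-No1. Within 129S1-No1 6761 genes passed, 2590 higher and 4171 lower in mHep, and within C57B6-No1 3898, 1802 higher and 2096 lower. In both, 2318 genes passed, and 2045 of them had the same sign, 786 up and 1259 down, against 319.7 and 599 for independent calls. The 3 eHep arrays of C57B6-No1 correlated at 0.934 to 0.994 and its mHep arrays at 0.911 to 0.962, against 0.989 or more in 129S1-No1. These p-values measure only the spread between arrays of 1 mouse. In 129S1-No1 the median of all genes was -0.37, and with the 75th percentile of detected probes it was 0.037, with 3779 higher and 2724 lower. In C57B6-No1 the corresponding medians were -0.09 and 0.041, and median scaling gave -0.20. The balance turned there too, with 2271 higher and 1874 lower by detected probes and 889 higher and 739 lower with normexp background. With slide as a block the counts were 3094 and 2912, and within the later scan 9935 and 4843. In 129S1-No1 the eHep arrays shared 1 slide and the mHep arrays another, so medium and slide coincided there. The slide term between these slides came from eHep 2-1 and eHep 2-2 alone, so the 3094 does not part medium from slide. Leaving out replicate 1, 2 or 3 gave 3931, 2091 and 6665 in 129S1-No1, and 1934, 1180 and 3704 in C57B6-No1. Simulated changes of log2 1, 2, 4 and 8 were recovered in 22%, 66%, 100% and 100% of genes in 129S1-No1, with 9 false calls.

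The change from eHep to mHep differed between the mice in genes of several kinds, among them inflammatory, cell cycle and metabolic genes. S100a9, a calcium-binding protein of inflamed tissue, changed by -2.38 in 129S1-No1, 11.35 in C57B6-No1 and 1.90 in 129S1-No2 (difference of C57B6-No1 from 129S1-No1 13.73 ± 0.61, adjusted p = 6.6e-07, n = 3 arrays per group). Ch25h, which makes 25-hydroxycholesterol, changed by -9.60 in 129S1-No1, 3.25 in C57B6-No1 and 3.17 in 129S1-No2 (difference 12.85 ± 1.46, adjusted p = 4.0e-04), and the alcohol dehydrogenase gene Adh1 by -3.26 in 129S1-No1, 8.84 in C57B6-No1 and 7.65 in 129S1-No2 (difference 12.11 ± 0.97). In the other direction, Apoa2, a high-density lipoprotein gene, changed by 10.60 in 129S1-No1, 0.37 in C57B6-No1 and 0.69 in 129S1-No2 (difference -10.22 ± 0.58), and Cps1, the first step of the urea cycle, had a difference of -7.42 ± 0.88. Further genes were S100a8 (9.54 ± 0.42), Bcl2l15 (9.09 ± 0.33), Sprr2h (8.99 ± 0.79), Paqr9 (-8.81 ± 0.61), Fibin (-8.12 ± 0.42), Slc27a2 (-7.23 ± 0.75) and Cxcl12 (-13.19 ± 0.91), a gene whose probes disagreed in the sign of the mean change over mice. By list, the test was chosen after these values were seen. Of the interferon response genes 15 of 23 changed more upward in C57B6-No1 and 19 did so adjusted over the list alone (median 2.74, adjusted p = 1.4e-05, adjusted p = 0.732 with an estimated correlation). The same direction was found in 10 of 25 acute phase genes, 17 adjusted over the list alone (median 2.72, adjusted p = 3.2e-05, adjusted p = 0.732 with an estimated correlation). Cell cycle genes fell less in C57B6-No1, with a more positive change in 15 of 27 S phase genes, 19 adjusted over the list alone (median 1.61, adjusted p = 5.5e-06, adjusted p = 0.732 with an estimated correlation). A more positive change was also found in 12 of 29 G2 and mitosis genes, 14 adjusted over the list alone (median 1.62, adjusted p = 8.2e-05, adjusted p = 0.732 with an estimated correlation). Likewise it was found in 9 of 20 NRF2 targets, 10 adjusted over the list alone (median 1.20, adjusted p = 0.00541, adjusted p = 0.732 with an estimated correlation). In macrophage markers it was found in 4 of 10 genes, 6 adjusted over the list alone (median 1.53, adjusted p = 9.7e-04, adjusted p = 0.732 with an estimated correlation). Of the glucose genes 7 of 14 changed more downward in C57B6-No1, 10 adjusted over the list alone (median -1.82, adjusted p = 1.7e-05, adjusted p = 0.732 with an estimated correlation), and of the urea cycle and amino acid genes 6 of 20 (median -0.83, adjusted p = 0.00541, adjusted p = 0.732 with an estimated correlation). The pericentral list (median 1.56, adjusted p = 0.0196) and the circadian list (median -0.49, adjusted p = 0.0317) also passed, again not with an estimated correlation. Some medians depended on the processing, with 0.52 for NRF2 targets by quantile normalization, and 0.81 for G2 and mitosis, 0.81 for macrophage markers and 0.76 for the pericentral list with normexp background. In each of the acute phase, NRF2 and pericentral lists 1 gene changed the other way, as did 1 urea cycle gene.

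Over all genes, 2463 of 14597 had a change that differed between C57B6-No1 and 129S1-No1, 1563 with a more positive and 900 with a more negative change in C57B6-No1. For 1904 of these (77.3%) the change in 129S1-No2 was closer to that of C57B6-No1, against 73.1% over all genes. The median of all genes was 0.25, and -0.018 with the 75th percentile of detected probes. Normexp background gave 478 higher and 171 lower. The count was 1209 with slide as a block, 5932 with scan as a block and 5490 within the later scan. Without replicate 1, 2 or 3 it was 287, 227 and 2680. Leaving out single arrays gave 1422, 1557 and 1413 without eHep 1-1, 1-2 and 1-3, 1527, 1580 and 1368 without mHep 1-1, 1-2 and 1-3, and 4850 without mHep 2-3. Simulated differences of log2 1, 2, 4 and 8 were recovered in 2%, 34%, 88% and 100% of genes, with 8 false calls.

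Over both media, liver genes were lower and biliary genes higher in C57B6-No1 than in 129S1-No1. Tm4sf1, a membrane protein of proliferating and vascular cells, was higher in C57B6-No1 (log2 difference 9.02 ± 0.29, adjusted p = 8.9e-09, n = 6 arrays per mouse), as were the protease inhibitor gene Serpinb1a (7.15 ± 0.30), Fstl1 (7.13 ± 0.40), Zfp536 (6.61 ± 0.65), Nat8l (6.58 ± 0.43) and Spint1 (6.57 ± 0.29). Lower in C57B6-No1 were Igsf23 (-6.89 ± 0.26), the lipoprotein gene Apoc1 (-6.84 ± 0.73), Fmo1 (-6.79 ± 0.47), prothrombin F2 (-6.61 ± 0.47), Atp10d (-6.24 ± 0.36) and the clotting factor gene F11 (-5.94 ± 0.21). By list, again with a test chosen after the values were seen, 18 of 22 plasma protein genes were lower (18 adjusted over the list alone, median -2.92, adjusted p = 7.7e-11, adjusted p = 0.269 with an estimated correlation). Further, 20 of 23 complement and coagulation genes were lower (20 adjusted over the list alone, median -2.85, adjusted p = 1.8e-10, adjusted p = 0.269 with an estimated correlation). Of the drug enzymes, 15 of 20 P450 genes were lower (17 adjusted over the list alone, median -1.58, adjusted p = 2.5e-07, adjusted p = 0.269 with an estimated correlation). By contrast 12 of 24 biliary and progenitor genes were higher (13 adjusted over the list alone, median 0.70, adjusted p = 9.7e-05, adjusted p = 0.269 with an estimated correlation), and 6 of 14 Notch pathway genes were higher (6 adjusted over the list alone, median 0.69, adjusted p = 0.00296, adjusted p = 0.269 with an estimated correlation). Against this, 3 biliary genes and 1 Notch gene were lower in C57B6-No1, and with normexp background the medians were 0.55 and 0.092. In all 5031 genes passed, 2519 higher and 2512 lower in C57B6-No1. Of 2745 with at least 2-fold difference, 1730 (63.0%) had the same sign between C57B6-No1 and 129S1-No2, against 51.8% over all genes. C57B6-No1 enters both differences, which favours the same sign by construction, so this share gives no support from 129S1-No2. Each strain label is carried by at most 2 mice, so mouse and strain were not told apart. The median of all genes was -0.073, and 0.061 with median scaling, which gave 3077 higher and 2002 lower. The count was 3105 with slide as a block, 6847 within the later scan, and 3074, 2368 and 5220 without replicate 1, 2 or 3.

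Some differences between the mice, named after their values were seen, concerned single genes and whole chromosomes. Cdkn2a and Cdkn2b, which encode inhibitors of the cell cycle, and their neighbour Mtap, of methionine salvage, were not well above background on either array of 129S1-No2. Cdkn2a had means of 1.99 in 129S1-No1, 1.44 in C57B6-No1 and -7.02 in 129S1-No2. For Cdkn2b they were 3.32, 4.67 and -6.84, and for Mtap 0.21, 0.97 and -7.88. Their probes lay on chromosome 4 (mm9), Mtap (NM_024433) from 88826213 to 88826272, Cdkn2a (NM_009877) from 88920545 to 88920604 and Cdkn2b (NM_007670) from 88952437 to 88952496. The nearby Mllt3, Focad and Klhl9 were above background on both arrays of 129S1-No2, as was Dmrta1 on the other side, which was so on 1 of 6 arrays of each of the others. Ifne, between Klhl9 and Mtap, was above background on 4 of 6 arrays of 129S1-No1, 1 of 6 of C57B6-No1 and 0 of 2 of 129S1-No2, and Elavl2 on 1, 2 and 0. On chromosome 19, 78.1% of genes in eHep and 80.2% in mHep were higher in 129S1-No1 than in the other mice. The median differences were 0.81 ± 0.07 and 0.57 ± 0.052. Here ± is the SE over genes and does not measure the spread between mice. Chromosome 4 was higher in 129S1-No2, by 0.49 in eHep and 0.50 in mHep. Other shifts were of like size in eHep or in mHep. They were chromosome 8 in 129S1-No1 (-0.34 in eHep and -0.55 in mHep) and chromosome 13 in 129S1-No1 (-0.58 and -0.041). Chromosome 4 in 129S1-No1 (-0.25 and -0.42) and chromosome 19 in 129S1-No2 (-0.55 and -0.35) were lower. Each mouse was set against the mean of the other 2, so the values of a chromosome are tied by construction. These last shifts are therefore no separate observations from the rises of chromosomes 19 and 4. The transcripts Ifi202b and H60a were above background on 6 of 6 arrays of 129S1-No1, 0 of 6 of C57B6-No1 and 2 of 2 of 129S1-No2. On the array with the eHep source name their levels were 5.11 and -2.29.

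**Figure D4:**
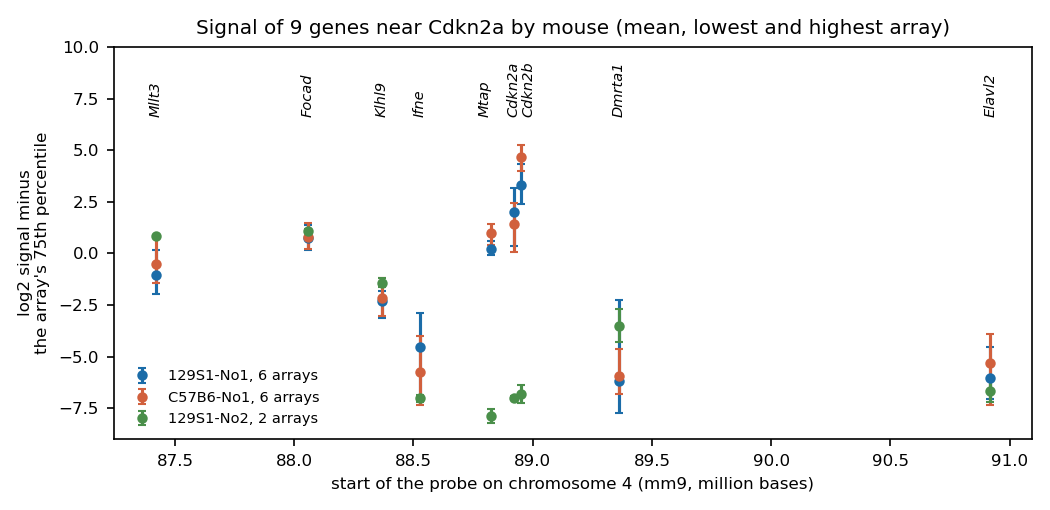
Signal of 9 genes near Cdkn2a on chromosome 4 in the 3 mice, mean with the lowest and highest array.

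**Figure D5:**
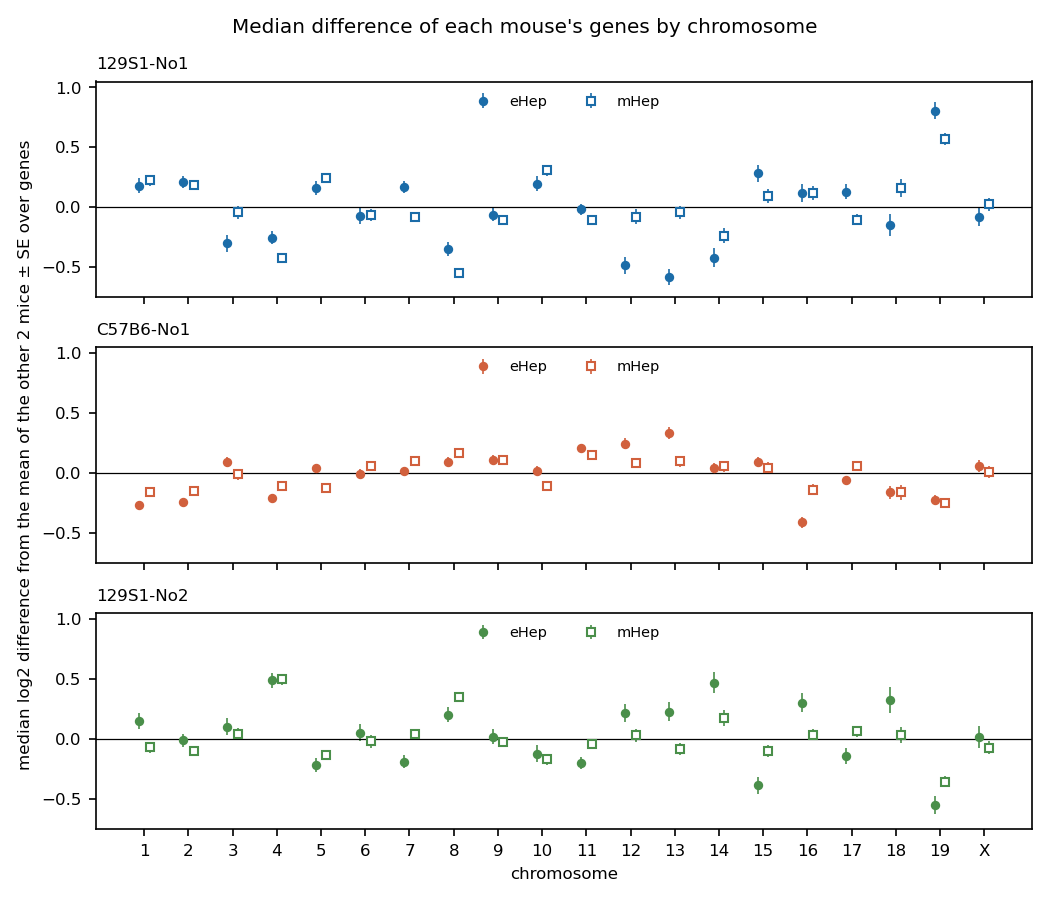
Median difference of the genes of each chromosome between 1 mouse and the mean of the other 2, by medium.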

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

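The tests in this part were chosen before the results were seen. Single arrays stood far from the other arrays of their group by Dixon's ratio in 4 of 58 groups of values, where chance alone gives about 1 in 20 if arrays are independent. Arrays of the same mouse are not, and eHep 3 and mHep 3 are the only arrays of 129S1-No2, so a difference between mice alone would set them apart. The level of Afp on eHep 3 was 1.37, against 4.17 to 5.003 on the other 6 eHep arrays. On mHep 3 the level of Serpina1d was 4.23, against 6.78 to 8.17 on the other 6 mHep arrays, and that of Cyp3a41a was -2.50, against 3.25 to 7.54 on the other 6. The 75th percentile of the log2 signal on mHep 2-1 was 7.998, against 9.15 to 9.51 on the other 6.

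The test of the difference between the changes in C57B6-No1 and 129S1-No1 passed for 2463 genes. Of 100 assignments of the arrays of each medium to the mice, the real one and 99 drawn ones, 1 gave as many, and the highest of the others gave 1772. The draws mix arrays of both mice and do not hold their difference in level fixed, so they are no fair test of a difference between changes, and chance stays open. The difference, as log2 change in C57B6-No1 minus change in 129S1-No1, was largest, among named genes, for S100a9 (13.73), Ch25h (12.85), Adh1 (12.11), S100a8 (9.54), Bcl2l15 (9.09) and Sprr2h (8.99). On the negative side it was largest for Cxcl12 (-13.19), Apoa2 (-10.22), Paqr9 (-8.81), Fibin (-8.12), Cps1 (-7.42) and Slc27a2 (-7.23). Secreted proteins also differed, with 5.51 for Saa2, 4.14 for Alb, 2.96 for Apoa1 and 2.45 for Apoc3. The keratins Krt19 and Krt7 differed by 4.07 and 3.84, the cyclin Ccnb1 by 2.26 and the cadherin Cdh1 by 1.77. Negative differences were found for Fabp1 (-2.01), Prrx2 (-2.32), Cyp3a11 (-2.87) and G6pc (-3.94). Each mouse was 1 animal, so mouse, strain and culture were not told apart, and no explanation was tested.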

How the results depend on the processing

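The fits within a scan, with scan as a block, with dim readings raised to the background limit, and of lists over 14 arrays with an estimated correlation were chosen only after the results were seen. Over the named genes and lists, 3075 of 3394 alternatives kept their side of the threshold, 251 lost the call and 68 gained it, and 0 were counted as reversed. Lists that did not pass could still change direction. Without 129S1-No1 the median of biliary genes went from -0.26 to 0.088 and that of NRF2 targets from -0.31 to 0.22. Of the counts and shares 149 stayed close, 64 moved and 1 reversed. The share of higher genes that fell was 1.76% and, without C57B6-No1, 0.781%, below that of other genes, with a range of 0.781 to 8.81% over mice left out. The cause of these shifts was not tested, though by construction the filters change the number of genes tested and leave-outs the number of arrays. Dim signal limits what can be seen: genes dark in a group give only bounds, and no filter let in genes near background.

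For mHep against eHep the 268 genes became 176 with normexp, 110 with quantile normalization, 521 with median scaling, 105 with detected probes, 110 with the table of the authors, 658 with no filter and 149 with the strict filter. They became 5024 with 14 arrays as samples, 3006 with slide as a block on those arrays, 1675 with a random mouse term, 470 in the later and 1520 in the earlier scan, and 513 to 829 with a mouse left out, 656 without 129S1-No2 for its labels. Without the mouse block 2 passed. Of 18 lists called, 0 remained with an estimated correlation, 7 with directional fry, 14 with fry in either direction (18 called), 18 over 14 arrays (20 called) and 6 over 14 arrays with an estimated correlation.

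Against primary cells, eHep (2279) and mHep (1514) gave 8511 and 8829 genes with no filter, 1139 and 667 with the strict filter, and 7780 and 7535 on single arrays with slide as a block. On single arrays a random mouse term gave 3912 and 3275, the C57B6 mouse 4959 and 4059, the earlier scan 5489 and 3997. On mouse means a mouse left out gave 429 to 2381 and 102 to 1568. Normexp gave 954 for mHep.

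Within 129S1-No1, C57B6-No1, for their changes and for their levels (6761, 3898, 2463 and 5031), normexp gave 3938, 1628, 649, 2608. Slide as a block gave 3094, 2912, 1209, 3105, scan as a block 9610, 5906, 5932, 6497, and leave-outs 2091 to 8186, 1180 to 5222, 227 to 4850 and 2368 to 5982. In 129S1-No1 no filter gave 12349, the changes 5490 in the later scan, and the levels 2745 with at least 2-fold. Where 1 array was left in a group it was assumed to vary like the others. With the replicate number as a block the counts were 8547, 4668, 4119, 2874, and arrays of the same number correlated at -0.076, -0.10 and -0.19 in 129S1-No1 and 0.60, -0.20 and 0.68 in C57B6-No1, so not every array fitted its own number best.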

Other observations

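The list tests within 1 mouse and the tests on the Cdkn2a locus, on chromosome 19 and on replicate 3 of C57B6-No1 were chosen only after the results were seen. Within the mice with 3 arrays per medium, genes of mesenchymal cells fell from eHep to mHep: 12 and 10 of 23 in 129S1-No1 and C57B6-No1, 12 and 11 adjusted over the list alone, with medians of -0.98 and -0.81. The list passed in C57B6-No1 (adjusted p = 0.00209, adjusted p = 0.135 with an estimated correlation) and not in 129S1-No1 (adjusted p = 0.399). In 129S1-No1 4 genes of that list rose, and the median was -0.44 with quantile normalization. Of the YAP targets 11 and 9 of 20 fell, 11 and 10 adjusted over the list alone, with medians of -0.83 and -0.76 (C57B6-No1 adjusted p = 0.00209, adjusted p = 0.265 with an estimated correlation), and the list did not pass in 129S1-No1 (adjusted p = 0.125, median -0.43 with detected probes). Of the p53 targets 15 and 11 of 24 fell, 15 and 11 adjusted over the list alone, with medians of -1.23 and -0.88 (C57B6-No1 adjusted p = 0.0253, adjusted p = 0.265 with an estimated correlation), while 4 and 2 rose and the list did not pass in 129S1-No1 (adjusted p = 0.0607). In 129S1-No2 the median was -0.11 for mesenchymal genes and -0.16 for p53 targets. For YAP targets it was 0.53 there, in the opposite direction.

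Of 23 interferon response genes, 7 fell and 3 rose from eHep to mHep within 129S1-No1 (median -0.90, adjusted p = 0.578, adjusted p = 0.887 with an estimated correlation). Within C57B6-No1 12 of them rose and 0 fell (median 1.81, adjusted p = 4.4e-07, adjusted p = 0.265 with an estimated correlation). Oas1a, chosen after its values were seen, fell by 3.91 in 129S1-No1 (adjusted p = 0.00344) and rose by 3.28 in C57B6-No1 (adjusted p = 0.0120). Lgr5, a receptor of stem cells and target of beta-catenin also chosen afterwards, was well above background on 7 eHep arrays and on 0 mHep arrays. Over the 3 mice Lgr5 did not pass (adjusted p = 0.120), and it passed within 129S1-No1 (adjusted p = 2.3e-04) and within C57B6-No1 (adjusted p = 0.00130).

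Other splits of the same arrays were counted. For mHep against eHep, 1 of 10 splits of the 6 means gave as many genes as the real 268, and the highest other gave 0, also among those that parted all 3 pairs of a mouse. Within 129S1-No1 1 of 10 splits gave as many as the real 6761, with 0 as the highest other. Within C57B6-No1 2 of 10 did, with 3898 genes in the real split and 5672 in the highest other, which set eHep 2-1, eHep 2-2 and mHep 2-1 against the rest, so that both arrays of the earlier scan fell on the same side, and points to a structure of the samples. With scan as a block the real count there was 5906, and within the later scan 4843. In these 3 cases 10 splits are too few for a share under 0.05. For levels in C57B6-No1 against 129S1-No1, 1 of 100 assignments gave as many as the real 5031, the highest other giving 1180. The arrays thus grouped by mouse. Since each mouse was 1 animal, the draws measure only the spread between arrays, and a chance difference between animals stays open.

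Cdkn2a, Cdkn2b and Mtap, the 3 genes most below the other mice among 33 dark in 129S1-No2 and bright on all arrays of the others, lay within 126284 bases. Since that choice fixes their readings in the other mice, genes were also picked without the arrays in question. Without the C57B6-No1 arrays of the earlier scan 195 genes were picked, these 3 again the most below, and 123 of the 195 were dark on both arrays left aside. Without the arrays of 129S1-No1 122 were picked, these 3 among the first 6, and 39 of the 122 were dark on all arrays left aside. The earlier scan is argued against, since 6 of 6 readings of the genes were well above background on the C57B6-No1 arrays of that scan. A 129S1 strain variant as the cause for these genes is argued against, since 18 of 18 readings were well above background in 129S1-No1. Random sets of as many genes held 3 within as short a span with a permutation p of 0.0005, consistent with loss of a stretch of chromosome 4, which remains a hypothesis. Ifne, between Klhl9 and Mtap, was dark in this mouse and above background on 4 and 1 of 6 arrays of the others, so the extent of such a loss stays open, as does regulation of the locus, and no DNA was measured.

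In 129S1-No1, genes of chromosome 19 were higher by a median of 0.68 over both media (429 genes), and it ranked first of 20 chromosomes on all 6 arrays. The scan batch is argued against, since within the later scan the difference from C57B6-No1 was 0.59. Gene density of the chromosome predicted 4.1e-04, and the observed value lay 3.1 residual SD above that line. An extra copy of chromosome 19 could raise its genes by 0.585, and the medians of 3 equal parts of the chromosome lay from 0.64 to 0.81. These lie above the range of 0.2 to 0.6 put down for an extra copy, which was itself chosen after the shift had been seen, so an extra copy stays open.

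Replicate 3 of C57B6-No1, from the earlier scan, differed over 2-fold from replicates 1 and 2 in 4649 genes in eHep and 4490 in mHep, and the shifts correlated at 0.680 between the media. Different probes of a gene shifted together, with r of at least 0.670, which argues against errors of single probes as the whole cause. Replicate 3 was the only replicate of this mouse in the earlier scan. An effect of scan or scanner that moves all probes of a gene alike was therefore not told apart and stays open. With ± as the SE over genes of a list, which does not measure the spread between cultures, lists were set against all genes. G2 and mitosis genes moved by 1.80 ± 0.33 in eHep and 0.72 ± 0.27 in mHep, and S phase genes by 0.99 ± 0.15 and -1.004 ± 0.20. More dividing cells could account for the first 3 of these values and not for the lower S phase genes in mHep, so they are argued against only as the whole cause in both media. Acute phase genes moved by -1.83 ± 0.45 and -0.77 ± 0.25. A difference between cultures or days stays open and was not tested.

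The array of mHep 3, whose source name says eHep, was given these checks. Without 129S1-No2, 656 genes passed between mHep and eHep, and 582 of them (88.7%) had the same sign in 129S1-No2. It correlated at 0.890 with eHep 3. The primary array correlated at 0.581 to 0.738 with eHep arrays and at 0.715 to 0.819 with mHep arrays. With mHep 3 itself it correlated at 0.720, below its values of 0.732 to 0.738 with the eHep arrays of 129S1-No1. This comparison therefore does not settle the label of mHep 3.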
